A study of Homo sapiens with 12 samples.

How the data were processed

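Gene expression was measured in BJ cells on 12 Illumina BeadChip arrays, all on 1 chip, in 4 groups of 3 arrays. Per the labels, total RNA was extracted with Qiagen RNeasy columns and turned into biotin-labelled cRNA with an Ambion MessageAmp kit. The groups were si-Control, si-EZH2, EZH2 re-expression and T350A re-expression. Every column of values matched 1 sample by its name, leaving 0 unmatched.

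The deposited non-normalized table gave 1 intensity per probe and array for 47231 probes. Its values were on a linear scale and were not background-subtracted. Beside each intensity, per the file headers, stood a detection p-value, which took steps of 1 in 770. The authors' normalized table held intensity values on a linear scale for 47229 probes. In every array these were a monotone function of that array's own raw signal (rank correlation 1), and the normalization method was not given in the sources used here. A single gene symbol was given for 30113 probes, several symbols for 8, and none for 17110. Symbols came from the deposited table, and no genome positions were used.

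The non-normalized intensities were background-corrected with the normexp model, using background estimated from the detection p-values, with an offset of 16. They were then quantile-normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3, with jsonlite 2.0.0 to read the labels). Probes with a detection p under 0.05 on at least 3 of the 12 arrays were tested. This left 23313 probes, of which 17151 had 1 symbol, covering 12640 genes. A linear model with 1 mean per group was fitted to all 12 arrays in limma, with empirical Bayes moderation (8 residual and 7.29 prior degrees of freedom). The moderated F-test compared the 4 groups, and 6 pairwise comparisons were made with limma's moderated test, 2-sided. Benjamini-Hochberg adjustment was applied over the tested probes of each comparison, and a probe was called at an adjusted p under 0.05. Errors on log2 differences are limma standard errors, and those on group means are SDs over 3 arrays. Where no array of a group detected a probe, the fold was computed against the detection limit of each array and given as a lower bound.

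The 17 gene lists were written from general knowledge before the data were examined, as were the comparisons, thresholds, alternatives and the rule for naming genes. They held PRC2 subunits, HOX genes, developmental regulators typically under PRC2, genes reported as repressed by EZH2, G2/M genes, DNA replication genes, p53 target genes, secreted inflammatory and senescence-associated genes, interferon-stimulated genes, fibroblast matrix genes, contractile and TGF-beta response genes, cholesterol synthesis genes, unfolded protein and amino acid response genes, hypoxia and glycolysis genes, and epithelial, endothelial and leukocyte markers. Each gene in a list was represented by 1 probe, the one with the highest mean. Lists were compared by camera with the other genes, each represented in the same way by 1 probe. Camera was run with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 102 list tests. Counts of called members were also computed with the adjustment over the list alone. The probes called in si-EZH2 minus si-Control were compared as sets by camera with all other tested probes. For these sets, fry tested whether the set moved on balance 1 way, which compares the set with no other probes. The camera and fry p-values of these sets were adjusted over 10 set tests, an adjustment added after the data were examined.

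Genes were named by a fixed rule. For si-EZH2 minus si-Control and the 3 comparisons among si-EZH2 and the re-expression groups, these were up to 8 genes with the largest rise and up to 8 with the largest fall among called probes with 1 symbol, taking for each gene the probe with the highest mean, whose 3 values in one group all lay above the 3 in the other. The limit was 4 and 4 for each re-expression against si-Control. Up to 4 members of each list with the smallest adjusted p and all PRC2 subunits could be named too. Y-linked genes and XIST were left out.

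Each result was recomputed under alternatives, 1 at a time. The stricter filter changed both the detection p and the number of arrays, and limma-trend was tried together with robust moderation. The alternatives were no background correction, median scaling, an offset of 50, the authors' values, no filter, detection p under 0.01 on all 12 arrays, limma-trend with robust moderation, array weights, only the groups compared, the replicate number as a block, chip section as a linear covariate, a fold of at least 1.5, 1 probe per gene, and leaving out each array. The pipeline was tested on simulated data with the spread of these arrays for si-EZH2 minus si-Control. It recovered 46 of 67 probes changed 1.5-fold (68.7%), 67 of 67 changed 2-fold and 66 of 66 changed 4-fold, and 5 of its 184 calls (2.72%) were unchanged probes. Probes detected per array ranged from 20658 to 21910, and the 3 arrays per group limited the precision.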

Results

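Gene expression was measured in BJ cells, an established line of human fibroblasts, to ask how phosphorylation of EZH2 at a threonine affects gene repression. EZH2 is the methyltransferase of Polycomb repressive complex 2 (PRC2), which silences genes by methylating histones. Cells were transduced with lentivirus for 72 h and then transfected with siRNA for 60 h. Control virus was combined with a control siRNA (si-Control) or with an siRNA against EZH2 (si-EZH2). Virus carrying an siRNA-resistant EZH2 (EZH2 re-expression) or its T350A form, in which alanine replaces the threonine (T350A re-expression), was combined with the siRNA against EZH2. Each group had 3 arrays, and their number limited the precision. Nothing in the labels states that replicates were separate cultures, so p-values measure only the spread between these samples.

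Between 20658 and 21910 of 47231 probes were detected on each array (43.7% to 46.4%), and median raw signals lay between 59.9 and 73.8. The median SD between replicates was 0.153 on the log2 scale. Among the 4 groups, 1591 of 23313 tested probes differed by limma's moderated F-test. That count was 870 and 873 without si-Control replicates 1 and 3, 1058, 995 and 1004 without EZH2 re-expression replicates 1, 2 and 3, and 697 with chip section as a covariate. It was higher, between 2796 and 3225, with no background correction, an offset of 50, the authors' values, limma-trend with robust moderation, or a stricter filter that asked for detection p under 0.01 on all 12 arrays.

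EZH2 itself was read by 3 probes. Probe ILMN_1708105 fell by 1.09 ± 0.13 on the log2 scale in si-EZH2 against si-Control (adjusted p = 0.000169) and stayed low in both re-expression groups, at 5.84 ± 0.15 with EZH2 and 5.91 ± 0.22 with T350A against 5.70 ± 0.12 in si-EZH2 (SD, n = 3). Its values were 6.69, 6.96 and 6.72 in si-Control and 5.56, 5.76 and 5.77 in si-EZH2. With re-expression they were 5.86, 5.99 and 5.68 for EZH2 and 5.90, 6.14 and 5.70 for T350A. Probe ILMN_1652913 read 6.43, 6.14 and 6.41 in si-Control, 5.46, 5.59 and 5.12 in si-EZH2, 8.46, 8.62 and 8.57 with EZH2 re-expression, and 7.98, 8.06 and 7.93 with T350A re-expression. It fell 1.91-fold on knockdown (adjusted p = 0.000507), rose 8.95-fold from si-EZH2 with EZH2 re-expression (adjusted p = 8.04e-10) and rose 6.07-fold with T350A re-expression (adjusted p = 1.46e-08). Probe ILMN_2364529 read 5.86, 5.42 and 5.62 in si-Control, 4.63, 4.59 and 4.73 in si-EZH2, where 0 of 3 arrays detected it, 8.50, 8.46 and 8.47 with EZH2, and 7.20, 7.04 and 7.32 with T350A. It was at least 1.61-fold lower after knockdown, and from there at least 11.6-fold higher with EZH2 and at least 4.72-fold higher with T350A. T350A transcript was lower than that of EZH2 re-expression by 1.29 ± 0.12 on this probe (2.45-fold, adjusted p = 0.000254). On ILMN_1652913 the difference was -0.56 ± 0.13, which did not pass the test (adjusted p = 0.211). Every T350A array lay below every EZH2 re-expression array on both probes. The other 10 measured PRC2 subunits were not called in any of the 6 comparisons.

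**Figure D1:**
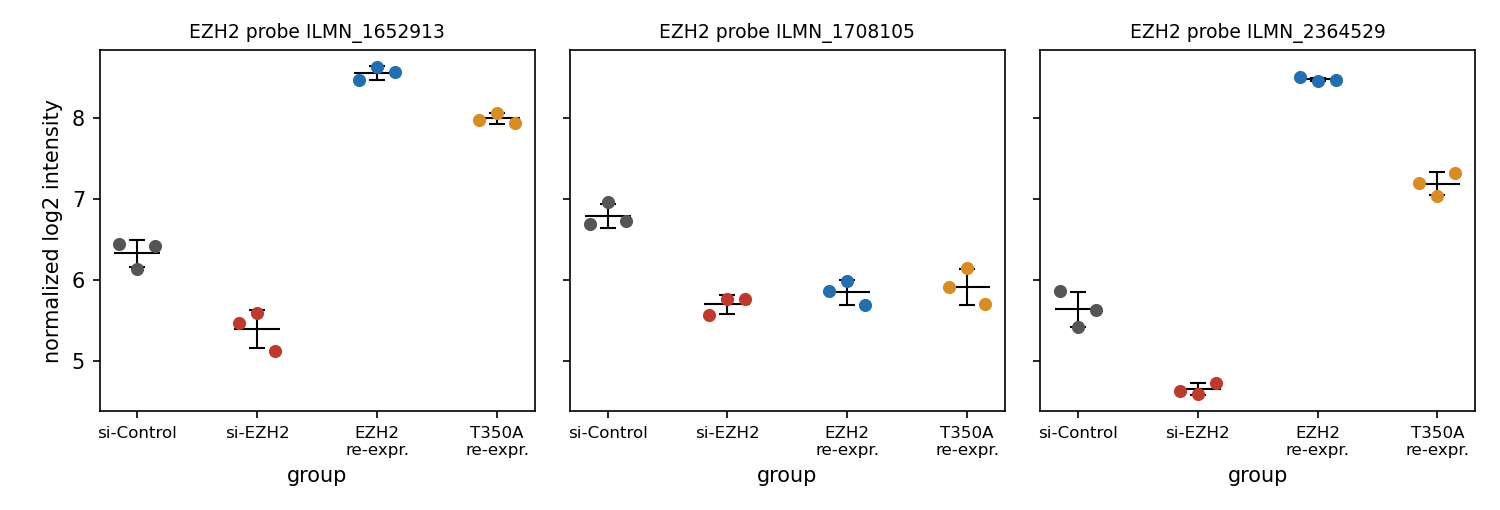
Normalized log2 intensity of the 3 EZH2 probes on each of the 12 arrays, by group (points, arrays; lines and bars, mean ± SD, n = 3). Probe ILMN_1708105 stayed at 5.84 and 5.91 with re-expression, while ILMN_1652913 reached 8.55 with EZH2 and 7.99 with T350A.

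Genes of inflammatory signalling were higher with the siRNA against EZH2 than with the control siRNA. Against si-Control, the tight junction gene CLDN1 rose by 2.75 ± 0.13 on the log2 scale (6.71-fold, adjusted p = 2.41e-08), the cytokine IL24 by 1.95 ± 0.12 (3.88-fold, adjusted p = 2.65e-07) and the neutrophil chemokine CXCL8 by 1.86 ± 0.098 (3.62-fold, adjusted p = 5.61e-08). Other rises were those of CXCL6 (1.77), the zinc transporter SLC39A8 (1.75), the oxysterol enzyme CH25H (1.74) and CXCL1 (1.59). The largest falls included ITGBL1, which no si-EZH2 array detected and which was at least 2.96-fold lower, VASN, a binder of TGF-beta (fell by 1.28), the matrix protease MMP11 (fell by 1.20), and the mitotic genes BIRC5 (fell by 1.06) and FOXM1 (fell by 0.96). The naming rule required all 3 arrays of one group to lie above all 3 of the other for each of these genes. These changes were not all reversed by EZH2 re-expression, so how far they passed through EZH2 is open. CLDN1 stayed at 7.47 (7.99 in si-EZH2, 5.24 in si-Control), whereas CXCL8 came down to 10.37 (11.76 in si-EZH2, 9.91 in si-Control). ANGPTL4 differed by 2.23 ± 0.47 (adjusted p = 0.0158), but its si-EZH2 arrays had an SD of 1.51, and its adjusted p was 0.0677 without si-Control replicate 1 and 0.0508 without si-Control replicate 3.

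In si-EZH2 minus si-Control, 19 of 26 measured inflammatory and senescence-associated genes rose, 0 fell and 7 were not called (21 rose adjusted over the list alone). Among them were CXCL8, CXCL6, IL1B (1.36) and the protease MMP3 (1.30), and the list's median was 0.80 (camera adjusted p = 6.65e-33). Of 32 interferon-stimulated genes, 15 rose and 0 fell (24 rose adjusted over the list alone), among them HERC5 (1.56), MX2 (0.89) and EPSTI1 (0.88), with a median of 0.45 (camera adjusted p = 1.07e-20). Of 26 G2/M genes, 5 fell and 0 rose (10 fell adjusted over the list alone), including BIRC5, and the median was -0.23 (camera adjusted p = 1.03e-07). That G2/M call was lost with the other form of the test (adjusted p = 0.181 with an estimated correlation). The mean over the list relative to si-Control was -0.39 and -0.41 on si-EZH2 replicates 1 and 3 but -0.031 on replicate 2.

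Across all 23313 probes, 663 were called in si-EZH2 minus si-Control, of which 363 rose and 300 fell, and 192 rose and 111 fell by at least 1.5-fold. The count was 396 and 440 without si-Control replicates 1 and 3, and 432, 427 and 405 without si-EZH2 replicates 1, 2 and 3. With chip section as a covariate it was 384, and between 1061 and 1199 with no background correction, an offset of 50, the authors' values, the stricter filter or limma-trend. With median scaling 39.1% of 660 called probes were higher, against 54.8% here.

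Re-expression of EZH2 lowered part of the inflammatory genes and raised part of the mitotic genes. Against si-EZH2, IL24 fell by 1.46 ± 0.12 on the log2 scale (adjusted p = 1.78e-05), CXCL8 by 1.40 ± 0.098 (adjusted p = 2.29e-06) and TNFSF18, a ligand of the tumour necrosis factor family, by 1.26 ± 0.13 (adjusted p = 0.00017). Hyaluronan synthase HAS2 fell by 1.00 and the protease MMP7 by 0.97. Besides EZH2, the rises included TMSB15A (0.99 ± 0.12), RNFT2 (0.99), the thymidine kinase TK1 (0.92), BIRC5 (0.87) and CD14 (0.85). By the naming rule, all 3 arrays of one group had to lie above all 3 of the other in each.

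In EZH2 re-expression minus si-EZH2, 10 of 26 G2/M genes rose and 0 fell (18 rose adjusted over the list alone), among them KIF20A (0.82), PBK (0.75) and PTTG1 (0.74), with a median of 0.45 (camera adjusted p = 3.73e-15; adjusted p = 0.0727 with an estimated correlation). That median ran from 0.326 to 0.571 over 23 alternatives. By the mean over the list, the rise was smaller against si-EZH2 replicate 2 than against the other si-EZH2 arrays. Of 26 inflammatory genes 10 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 1.64e-09). IL1A fell by 0.77 and IL1B by 0.69, whereas MMP3 rose by a further 0.72 ± 0.098. Of 32 fibroblast matrix genes 6 fell and 0 rose (7 and 1 adjusted over the list alone), including the collagens COL15A1 (fell by 0.86) and COL6A1 (fell by 0.83) and fibromodulin FMOD (fell by 0.72), with a median of -0.21 (camera adjusted p = 1.63e-07). Interferon-stimulated genes had 3 falls and 0 rises among 32 (5 and 1 adjusted over the list alone) and a median of -0.20 (camera adjusted p = 0.00181; adjusted p = 0.157 with an estimated correlation).

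Between EZH2 re-expression and si-EZH2, 671 of 23313 probes were called, 350 higher and 321 lower. Without si-EZH2 replicates 1 and 3 the count was 203 and 205, and without EZH2 re-expression replicates 1, 2 and 3 it was 264, 253 and 267. It was 354 with chip section as a covariate, and between 1339 and 1489 under the same 5 settings that raised the knockdown count. Median scaling made 37.6% of 631 called probes higher, against 52.2% here.

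T350A re-expression lowered the same leading cytokines with fewer calls. Against si-EZH2, IL24 fell by 1.06 ± 0.12 on the log2 scale (2.09-fold, adjusted p = 0.00166) and CXCL8 by 0.78 ± 0.098 (1.72-fold, adjusted p = 0.00377). In each, all 3 arrays of one group lay below all 3 of the other, as the naming rule required. Beside EZH2, the other genes named by the rule were RNFT2 (0.75), MGP (0.64) and UROS (0.58), which rose, and RSPO3, IL1A, SLC39A8, STC1, PTPRN and YKT6, which fell. Each of these 9 calls was lost in 5 to 11 of the 12 fits that left out 1 array, whereas those of EZH2, IL24 and CXCL8 held in all 12. CXCL8 had an adjusted p of 0.0653 when only the 2 groups compared were fitted. Inflammatory genes had 3 falls and 0 rises among 26 (11 and 0 adjusted over the list alone) and a median of -0.26 (camera adjusted p = 2e-10).

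In T350A re-expression minus si-EZH2, 24 of 23313 probes were called by limma, 11 higher and 13 lower, and 3200 had an unadjusted p under 0.05. The count was 9 without si-Control replicate 3, 5 and 8 without si-EZH2 replicates 1 and 3, 11, 14 and 9 without EZH2 re-expression replicates 1, 2 and 3, and 10 and 6 without T350A re-expression replicates 1 and 2. It reached 420 with an offset of 50, and 57.0% of the 379 probes called on the authors' values were higher, against 45.8% here. The G2/M median was 0.17 with 0 of 26 called (1 rose adjusted over the list alone), and its camera adjusted p of 0.00187 became 0.0661 without si-EZH2 replicate 3 (adjusted p = 0.359 with an estimated correlation). That median ran from 0.0902 to 0.244 over 23 alternatives. By the mean over the list, si-EZH2 replicate 2 lay above every T350A array, so the rise rests on si-EZH2 replicates 1 and 3. Interferon-stimulated genes had a median of -0.10 and 0 of 32 called (1 fell adjusted over the list alone; camera adjusted p = 0.00303; adjusted p = 0.166 with an estimated correlation). Fibroblast matrix genes had a median of -0.14 with 1 rise and 0 falls among 32 (1 and 1 adjusted over the list alone; camera adjusted p = 0.0026).

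The comparison of T350A with EZH2 re-expression asks what the loss of the threonine changes, and it was made at a lower T350A transcript level. Of 23313 probes, 2 were called by limma and 2050 had an unadjusted p under 0.05. Both were lower in T350A: EZH2 probe ILMN_2364529 and probe ILMN_1721535 of COG5, a Golgi tethering subunit. COG5 was named after its values were seen, because the naming rule takes the brightest probe of a gene. That brightest probe, ILMN_2399877, differed by 0.04 ± 0.12 (adjusted p = 0.95), and the remaining COG5 probe, ILMN_1698621, by -0.74 ± 0.16 (adjusted p = 0.194). On ILMN_1721535 COG5 fell by 0.83 ± 0.10 on the log2 scale (adjusted p = 0.00527), with all 3 T350A arrays below all 3 EZH2 arrays, and its means were 7.90 in si-Control, 7.43 in si-EZH2, 8.01 with EZH2 and 7.18 with T350A. Its adjusted p was 0.0532 without EZH2 re-expression replicate 1, and 0.0508 and 0.0509 without T350A re-expression replicates 1 and 3, where the count of called probes was 1. MMP3 differed by -0.62 ± 0.098 and CXCL8 by 0.62 ± 0.098, and neither passed the test (adjusted p = 0.0637 for each). Counts rose to 29 without background correction (34.5% higher), 43 with an offset of 50 (41.9% higher), 32 on the authors' values (37.5% higher), 14 with the stricter filter (42.9% higher) and 50 with limma-trend and robust moderation (48% higher).

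G2/M genes were lower with T350A than with EZH2 re-expression in 25 of 26 cases, with a median of -0.33 (camera adjusted p = 3.54e-15; adjusted p = 0.0727 with an estimated correlation). None of the 26 was called over all probes by limma (10 fell adjusted over the list alone), and the smallest adjusted p was that of CCNB2 (-0.55 ± 0.12, adjusted p = 0.194). Relative to si-Control, the mean over the list was 0.19, 0.21 and 0.16 on the EZH2 re-expression arrays and -0.15, -0.16 and -0.096 on the T350A arrays. The exact permutation test of these means gave p = 0.1, 2-sided, the smallest that 3 arrays against 3 allow. Other lists reached the same p and are thus not set apart from the G2/M genes by it. Among them were the p53 target genes, the hypoxia and glycolysis genes and the genes reported as repressed by EZH2, none of which passed by camera. DNA replication genes had a median of -0.13 and 20 of 24 lower (0 called, 1 fell adjusted over the list alone; camera adjusted p = 0.00722; adjusted p = 0.218 with an estimated correlation). Fibroblast matrix genes were higher with T350A in 24 of 32 cases, with a median of 0.077 (0 called, 5 rose adjusted over the list alone; camera adjusted p = 0.000116). Against si-Control their median was -0.16 with EZH2 re-expression (1 rose and 6 fell, camera adjusted p = 0.0208, and 0.0848 with an estimated correlation). With T350A it was -0.067 (2 rose and 0 fell, camera adjusted p = 0.748). Inflammatory genes had a median of 0.060 (0 called, 2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.197) and interferon-stimulated genes one of 0.022 (0 of 32 called over all probes or over the list alone; camera adjusted p = 0.448).

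**Figure D2:**
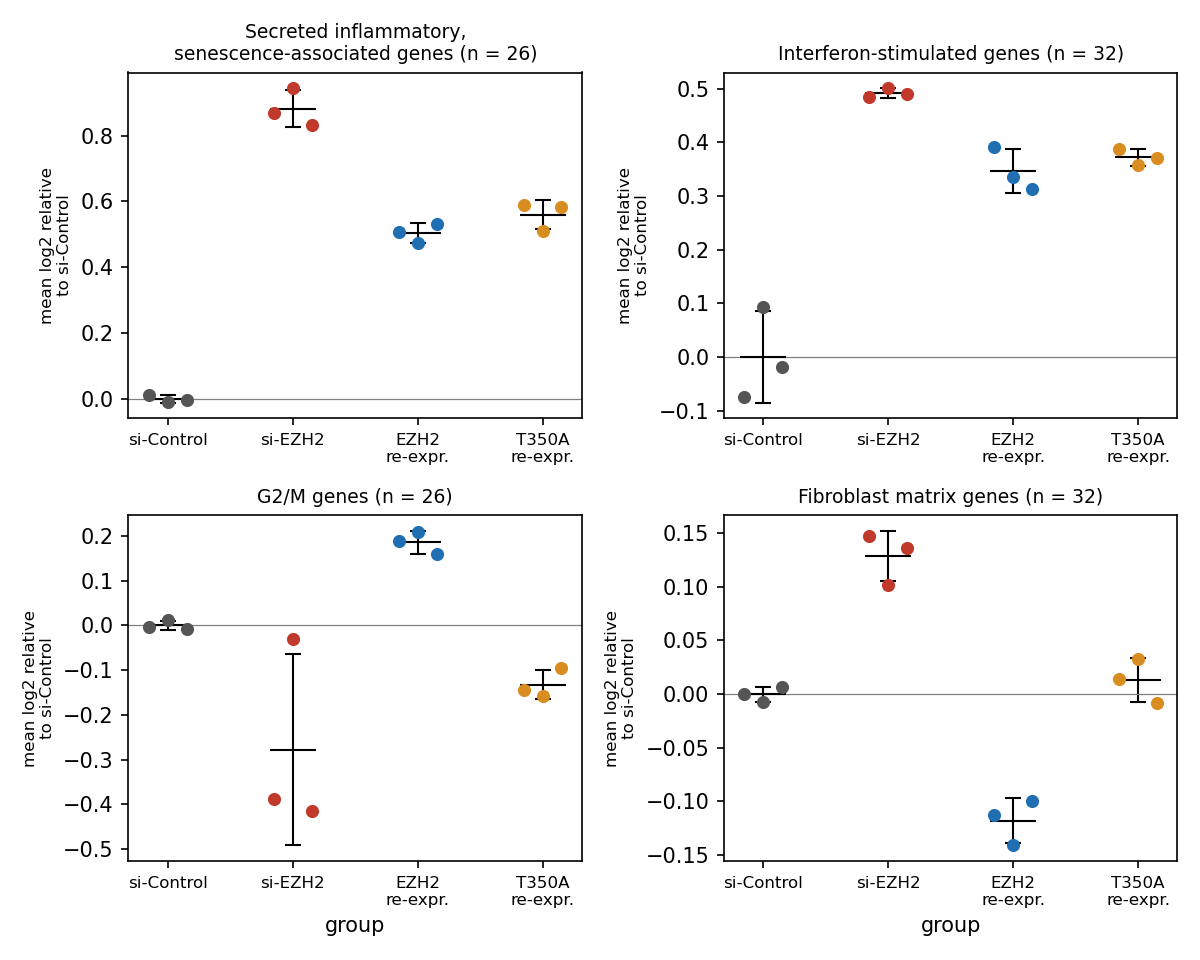
Mean log2 intensity of gene lists on each array relative to the si-Control mean (points, arrays; lines and bars, mean ± SD, n = 3). G2/M genes lay between 0.16 and 0.21 on EZH2 re-expression arrays and between -0.16 and -0.096 on T350A arrays.

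Probes that responded to the knockdown were followed as 2 sets. The 363 raised probes, with a median of 0.60 in si-EZH2 minus si-Control, had a median of -0.22 in EZH2 re-expression minus si-EZH2 (82.1% lower; camera adjusted p = 5.4e-22) and of -0.20 with T350A (87.6% lower; camera adjusted p = 2.22e-27). The 300 lowered probes, with a median of -0.54, had medians of 0.16 (camera adjusted p = 1.16e-13) and 0.15 (camera adjusted p = 7.99e-20). All 4 calls held with an estimated correlation, and the largest of those adjusted p was 1.55e-05. These comparisons share the si-EZH2 arrays with the choice of probes. With probes chosen on 2 si-EZH2 arrays and measured against the left-out one, the mean medians were -0.22 with EZH2 and -0.19 with T350A for the raised probes, and 0.082 and 0.11 for the lowered ones. Without si-EZH2 replicate 2, the lowered set had a median of 0.25 with T350A in place of 0.15. In 20 simulations with no effect of re-expression the raised sets had mean medians of -0.022 with EZH2 and -0.023 with T350A, and the lowered sets 0.022 and 0.023. The simulations gave called probes their estimated knockdown shift and all other probes a shift of 0. They thus left out weaker shifts and may understate the bias from the shared arrays. They called means of 306 raised and 241 lowered probes, against 363 and 300 here. Of the raised probes, 67 were called lower with EZH2 re-expression, where n1 × n2 / N gave 5 and the simulations 0, and 10 were called still higher, where n1 × n2 / N gave 5.45. Of the lowered probes, 37 were called higher, where n1 × n2 / N gave 4.5 and the simulations a mean of 0.050, and 1 was called still lower, where n1 × n2 / N gave 4.13. The value n1 × n2 / N takes the comparisons as independent, although they share the si-EZH2 arrays, so neither reference covers the whole bias.

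With re-expression the knockdown-responsive probes remained away from si-Control. The raised set had a median of 0.41 in EZH2 re-expression minus si-Control and of 0.43 with T350A, and the lowered set -0.40 with each. Between T350A and EZH2 re-expression, which shared no array with the choice of probes, the raised set had a median of 0.0099 (quartiles -0.11 and 0.13; camera adjusted p = 0.422, fry adjusted p = 0.368). The lowered set had a median of -0.00074 but a mean of 0.00073 and a positive camera direction (quartiles -0.11 and 0.14; camera adjusted p = 0.776, fry adjusted p = 0.988). Before adjustment, the camera test of the raised set passed 0.05 when only the 2 groups compared were fitted (median 0.026), for probes with a fold of at least 1.5 (median 0.030), and without si-Control replicate 1 (median 0.025) or 3 (median 0.030).

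**Figure D3:**
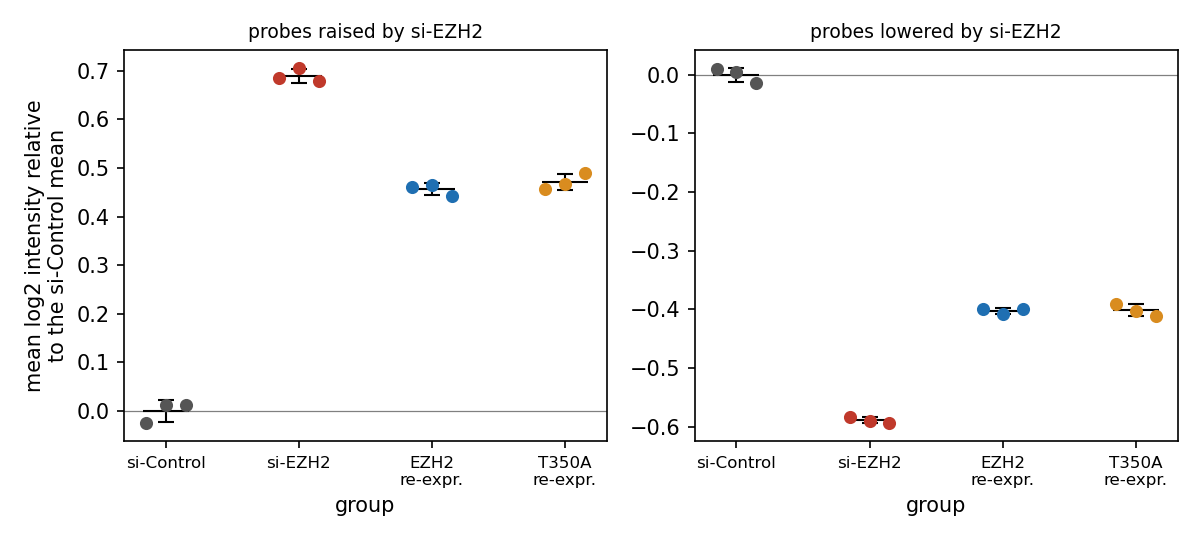
Mean log2 intensity of the 363 probes raised and the 300 probes lowered by si-EZH2, on each array relative to the si-Control mean (points, arrays; lines and bars, mean ± SD, n = 3). The median of the raised set against si-Control was 0.41 with EZH2 and 0.43 with T350A, below the 0.60 of si-EZH2.

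Both re-expression groups were compared with si-Control. EZH2 probe ILMN_1652913 read 4.68-fold above si-Control with EZH2 re-expression and 3.17-fold with T350A. ILMN_2364529 read 7.18-fold and 2.93-fold above, so transcript on these probes was above the control level, not restored to it. Differences already seen in si-EZH2 changed in size. With EZH2 re-expression MMP3 moved further from si-Control (13.83 against 13.1 in si-EZH2 and 11.8 in si-Control), while CLDN1 moved closer (7.47 against 7.99 in si-EZH2). With EZH2 re-expression, CLDN1 was 2.23 ± 0.13 above si-Control on the log2 scale (adjusted p = 1.32e-07), MMP3 2.02 ± 0.098 above (adjusted p = 1.51e-08) and the protease inhibitor TFPI2 1.72 ± 0.11 above (adjusted p = 3.63e-07). VASN fell by 1.36, the iron-sulfur assembly gene ISCA1 by 1.25 and STAT5B by 1.02. With T350A re-expression, CLDN1 (2.21 ± 0.13), MGP, an inhibitor of calcification (1.60 ± 0.10), and HERC5 (1.46 ± 0.13) rose, and ISCA1 fell by 0.99 and SLC8A1 by 0.98. CDKN2A, a cell cycle inhibitor known as a target of EZH2, rose by 0.65 ± 0.12 with EZH2 (adjusted p = 0.00549) and by 0.74 ± 0.12 with T350A (adjusted p = 0.00472). In each of the genes chosen for the size of their change, all 3 arrays of one group lay above all 3 of the other, as the naming rule required.

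Against si-Control, 13 of 26 inflammatory genes rose and 0 fell with EZH2 re-expression (19 rose adjusted over the list alone; median 0.46, camera adjusted p = 1.92e-11), and 13 rose and 0 fell with T350A (20 rose adjusted over the list alone; median 0.51, camera adjusted p = 9.85e-17). Of 32 interferon-stimulated genes, 13 rose with EZH2 (18 adjusted over the list alone; median 0.28, camera adjusted p = 1.85e-09) and 11 with T350A (21 adjusted over the list alone; median 0.39, camera adjusted p = 6.63e-13). G2/M genes had a median of 0.19 with EZH2 (5 rose and 1 fell, 8 and 1 adjusted over the list alone; camera adjusted p = 0.0138; adjusted p = 0.469 with an estimated correlation; camera adjusted p = 0.0823 and median 0.155 with chip section as a covariate; median 0.0996 with median scaling) and of -0.18 with T350A (0 rose and 1 fell, 0 and 4 adjusted over the list alone; camera adjusted p = 0.0205; adjusted p = 0.498 with an estimated correlation).

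EZH2 re-expression minus si-Control gave 1688 called probes, 839 higher and 849 lower, and T350A re-expression minus si-Control gave 830, 407 higher and 423 lower. The first count was 843 and 890 without si-Control replicates 1 and 3, and 922, 823 and 878 without EZH2 re-expression replicates 1, 2 and 3. The second was 361 and 344 without those si-Control arrays, and 408, 438 and 469 without T350A re-expression replicates 1, 2 and 3. Chip sections ran largely with group: si-Control lay in A, C and F, si-EZH2 in E, G and H, and EZH2 re-expression in I, K and J. Only T350A re-expression was spread, in B, D and L. With section as a covariate 282 probes were called in place of 1688, against 597 in place of 830. Because section and group overlap, an effect of position cannot be told apart here from a loss of precision. An offset of 50, the authors' values and limma-trend gave 2704, 2570 and 2603 for EZH2 re-expression, and 1650, 1516 and 1536 for T350A re-expression, for which no background correction gave 1482 and the stricter filter 1498. With median scaling 23.6% of 2114 and 27.2% of 1000 called probes were higher, against 49.7% and 49.0% here.

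Lists of typical PRC2 targets were compared in the knockdown and the re-expressions. Measured were 13 of 39 HOX genes, 23 of 56 developmental regulators and 13 of 22 genes reported as repressed by EZH2. Members without a probe that passed the detection filter were not tested, so these results do not cover targets that stayed below detection. After knockdown, 0 of 13 measured HOX genes were called over all probes or over the list alone (median -0.051, camera adjusted p = 0.595). Of 23 developmental regulators 1 rose and 1 fell, with the same counts adjusted over the list alone (median -0.069, camera adjusted p = 0.288). MSX2 was the riser (0.59 ± 0.13, adjusted p = 0.0215) and IRX5 the faller (-0.40), and every fit that left out a si-Control or si-EZH2 array ended the call of IRX5 (adjusted p 0.0645, 0.0557 and 0.126 without si-Control replicates 1, 2 and 3, and 0.0936, 0.104 and 0.0553 without si-EZH2 replicates 1, 2 and 3). MSX2 lost its call without si-Control replicates 2 and 3 (adjusted p 0.0912 and 0.0892) and without si-EZH2 replicates 1 and 3 (0.0693 and 0.0885). Of 13 genes reported as repressed by EZH2, 0 rose and 1 fell (1 and 4 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.252). The faller was the cell cycle inhibitor CDKN1C (-0.61 ± 0.12, adjusted p = 0.0112, and 0.0598 without si-Control replicate 1). Among 11 PRC2 subunits EZH2 alone was called, over all probes and over the list alone, and the list's median of 0.058 had a mean of -0.048 and a negative camera direction (camera adjusted p = 0.928).

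In EZH2 re-expression minus si-Control, 3 of 23 developmental regulators fell and 0 rose (7 fell adjusted over the list alone), and 18 of 23 were lower. The median was -0.13 (camera adjusted p = 0.0191; adjusted p = 0.123 with an estimated correlation), and the camera adjusted p was 0.0669 without EZH2 re-expression replicate 2, 0.0849 with chip section as a covariate and 0.0857 with no filter. Over 23 alternatives the median ran from -0.182 with median scaling to -0.0217 with no filter. The falls were those of LHX2 (-0.64 ± 0.11, adjusted p = 0.00372), TBX2 (-0.46, adjusted p = 0.0214) and IRX5 (-0.36, adjusted p = 0.0309). Without si-Control replicates 1 and 3 the adjusted p was 0.0903 and 0.0756 for TBX2 and 0.0608 and 0.116 for IRX5. Without EZH2 re-expression replicates 1 and 2 it was 0.0626 and 0.078 for TBX2 and 0.0829 and 0.0612 for IRX5, for which it was 0.102 without replicate 3. Of 13 genes reported as repressed by EZH2, CDKN2A rose and 3 fell (4 and 5 adjusted over the list alone), namely IGFBP3 (-0.74), CDKN1C (-0.62) and PEBP1 (-0.60). That list's median of 0.080 had a mean of -0.073 and a negative camera direction (camera adjusted p = 0.583). With chip section as a covariate the calls of LHX2, TBX2, IRX5, IGFBP3, CDKN1C and PEBP1 were lost. Of 13 HOX genes 1 rose and 0 fell in EZH2 re-expression minus si-Control (2 and 0 adjusted over the list alone). Their median was -0.054 with a mean of 0.025 (camera adjusted p = 0.892).

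Between T350A and EZH2 re-expression, the developmental regulators had a median of 0.085 with 17 of 23 higher (0 called over all probes or the list alone; camera adjusted p = 0.0384; adjusted p = 0.161 with an estimated correlation). The camera adjusted p was 0.237 without EZH2 re-expression replicate 2, and 0.0698 and 0.0882 without T350A re-expression replicates 1 and 2. It was 0.156 with chip section as a covariate, 0.148 with no filter and 0.0543 with the stricter filter. HOX genes had a median of -0.0048 with a mean of 0.0066 (0 of 13 called over all probes or the list alone; camera adjusted p = 0.998), and genes reported as repressed by EZH2 a median of 0.060 (0 of 13 called, 1 rose adjusted over the list alone; camera adjusted p = 0.431).

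Among the remaining lists, the call of the unfolded protein genes alone held with an estimated correlation after knockdown. Unfolded protein and amino acid response genes had a median of 0.14 with 2 of 25 higher by the test (4 adjusted over the list alone; camera adjusted p = 0.00296), led by the chaperone DNAJB9 (0.74 ± 0.13, adjusted p = 0.00446). Fibroblast matrix genes had a median of 0.093 with 2 rises and 1 fall among 32 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0158; adjusted p = 0.0727 with an estimated correlation). Contractile and TGF-beta response genes had a median of 0.14 with 2 of 17 risen (4 adjusted over the list alone; camera adjusted p = 0.0112; adjusted p = 0.0727 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.21 with 1 rise and 1 fall among 16 (3 and 1 adjusted over the list alone; camera adjusted p = 0.0114; adjusted p = 0.123 with an estimated correlation). The camera adjusted p was 0.0749 with the stricter filter, and the mean over the list relative to si-Control was 0.419 on si-EZH2 replicate 2 against 0.187 and 0.219 on replicates 1 and 3. Cholesterol synthesis genes had a median of -0.17 with 3 of 20 fallen (4 adjusted over the list alone; camera adjusted p = 0.0191; adjusted p = 0.161 with an estimated correlation), and the camera adjusted p was 0.0624 without si-Control replicate 1, 0.0916 without si-EZH2 replicate 1 and 0.0514 with chip section as a covariate. The p53 target genes had a median of 0.13 with 2 of 22 risen (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0205; adjusted p = 0.235 with an estimated correlation), and the camera adjusted p was 0.0546 without si-Control replicate 3 and 0.125 without si-EZH2 replicate 1. DNA replication genes had a median of 0.045 with 0 of 24 called over all probes or the list alone (camera adjusted p = 0.832).

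Markers of other cell types were not called after knockdown. Of the epithelial and keratinocyte markers 10 were measured and 0 called over all probes or the list alone (median -0.17, camera adjusted p = 0.0805). Of the endothelial markers 2 were measured and 0 called over all probes or the list alone (median 0.085, camera adjusted p = 0.7), and of the leukocyte markers 4 were measured and 0 called (1 fell adjusted over the list alone; median -0.054, camera adjusted p = 0.431). With EZH2 re-expression 1 of the 10 epithelial and keratinocyte markers rose against si-EZH2 (camera adjusted p = 0.201) and 1 against si-Control (camera adjusted p = 0.883). In T350A re-expression minus si-Control 1 of them fell (camera adjusted p = 0.407). In EZH2 and T350A re-expression minus si-EZH2 the leukocyte markers had medians of 0.19 and 0.23, with 2 rises and then 0 (2 and 2 adjusted over the list alone). Their camera adjusted p of 0.0442 and 0.0209 (adjusted p = 0.181 and 0.156 with an estimated correlation) passed the threshold in 12 and 19 of 23 alternatives. The first was 0.0541 without si-Control replicate 3, 0.0915 and 0.054 without si-EZH2 replicates 2 and 3, and 0.151 without EZH2 re-expression replicate 1, and its median was -0.00351 with no filter on dim probes. The second was 0.0611 without si-EZH2 replicate 2 and 0.0834 without T350A re-expression replicate 2. The camera calls of gene lists given here that also held with an estimated correlation were those of the inflammatory genes in both re-expressions against si-EZH2 and in all groups against si-Control, of the interferon-stimulated genes in all groups against si-Control, of the matrix genes in both re-expressions against si-EZH2 and in T350A against EZH2 re-expression, and of the unfolded protein genes after knockdown.

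**Figure D4:**
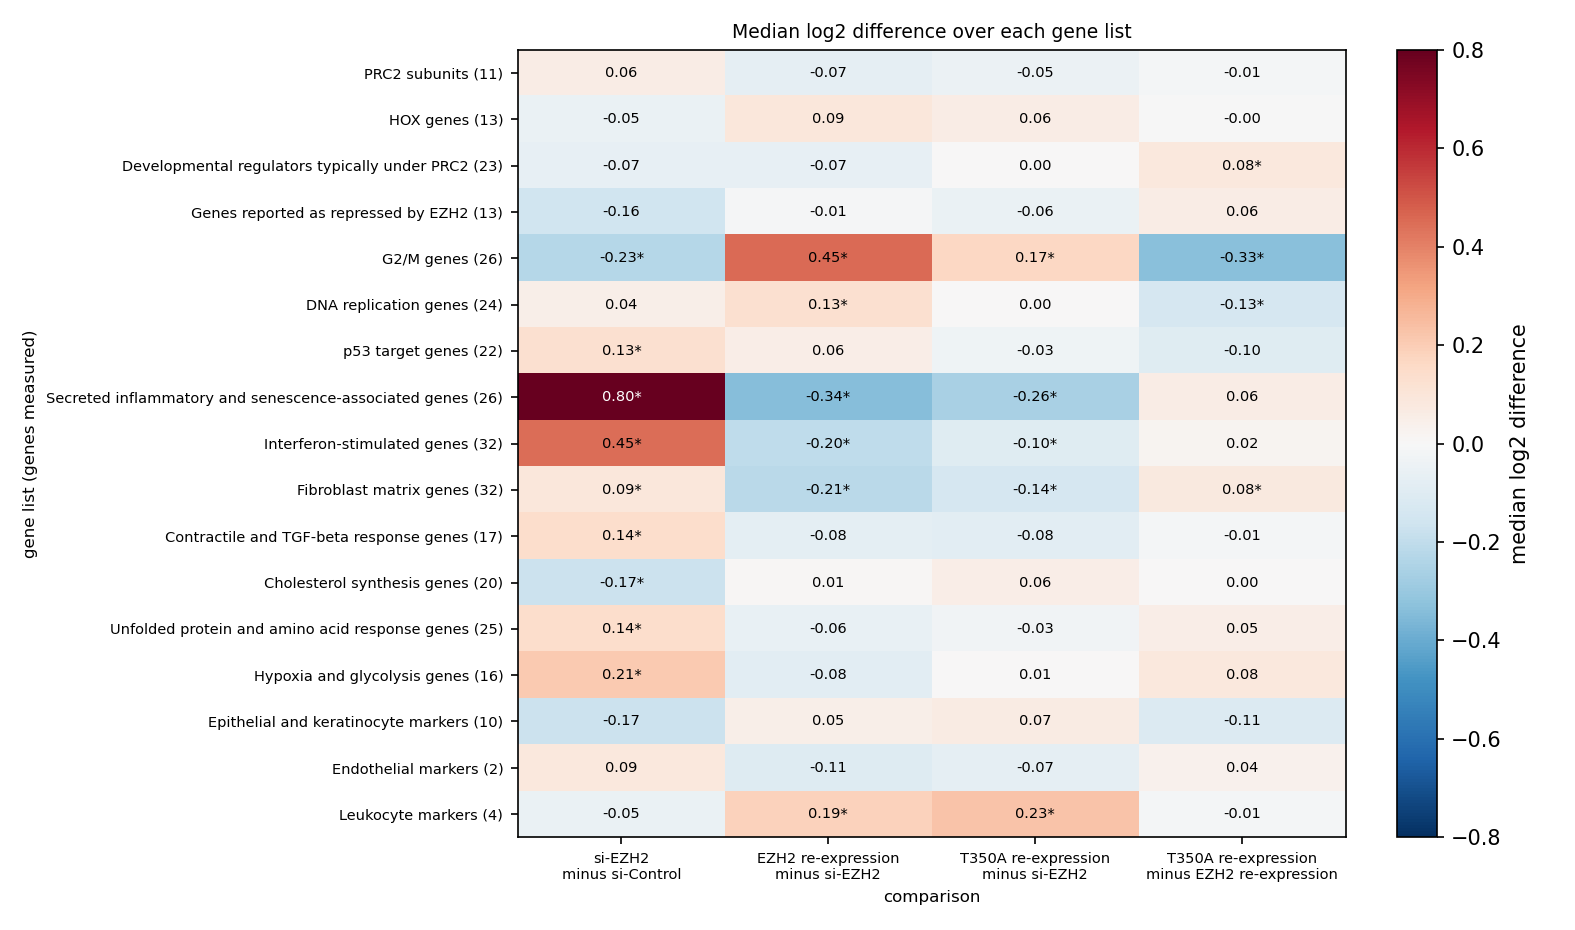
Median log2 difference of each of the 17 gene lists in 4 comparisons, with the number of measured genes in brackets and a star where the camera adjusted p with the preset correlation was under 0.05. Inflammatory genes had medians of 0.80 after knockdown, -0.34 and -0.26 with re-expression against si-EZH2, and 0.060 between the re-expressions.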

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

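The test of a lower level of re-expressed transcript was chosen only after the result was seen, and the other tests of this part were set beforehand.

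Of all the results, 6 differed between T350A and EZH2 re-expression by a direct test of that difference, at a preset camera correlation for the lists. EZH2 probe ILMN_2364529 was lower with T350A by a log2 difference of -1.29. COG5 had a log2 difference of -0.83 on 1 of its 3 probes, against 0.04 on its brightest probe, with a call that was lost in 3 fits that left out 1 array. G2/M genes had a median of -0.33, DNA replication genes one of -0.13, fibroblast matrix genes one of 0.077 and developmental regulators one of 0.085. With an estimated correlation only the matrix genes stayed past the threshold (adjusted p = 0.0126). For the count of 2 called probes, 10 splits of the 6 arrays are too few for a share under 0.05. In that comparison 1 split, the real one, gave as many, and the highest of the others gave 1.

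The lower G2/M genes with T350A were weighed further. Normalization between arrays as the whole cause was argued against by the 4 other normalizations, whose highest median was -0.26. A linear effect of position on the chip as the whole cause was argued against by a median of -0.31 with section as a covariate (camera adjusted p = 1.31e-11 at the preset correlation). The T350A arrays lay in B, D and L and those of EZH2 re-expression in I, K and J. An effect of position that is not linear is thus not covered. A lower level of re-expressed transcript cannot be told apart from the mutation, since every T350A array held less EZH2 mRNA than every EZH2 re-expression array on both probes taken to read the transgene. The smaller of their mean log2 differences was -0.56 (adjusted p = 0.211). These probes were picked after their values were seen. A loss of the phosphorylated threonine, the difference the design names, stays open and may act together with the transcript level.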

How the results depend on the processing

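All alternatives of this part were set before the data were examined, and in 0 called results did the direction of the test turn. The median of the leukocyte markers in EZH2 re-expression minus si-EZH2 turned from 0.187 to -0.00351 with no filter, where their call was lost. COG5 was added to the genes followed after its values were seen.

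Without background correction, 2958 probes differed among groups, and the counts were 1098 (si-EZH2 minus si-Control), 1361 (EZH2 re-expression minus si-EZH2), 335 (T350A re-expression minus si-EZH2), 29 (T350A minus EZH2 re-expression) and 1482 (T350A re-expression minus si-Control). In the same order, with EZH2 re-expression minus si-Control put before the last, an offset of 50 gave 3225, 1199, 1489, 420, 43, 2704 and 1650. The authors' values gave 3026, 1102, 1353, 379, 32, 2570 and 1516, and limma-trend with robust moderation 3107, 1154, 1430, 407, 50, 2603 and 1536. A detection p under 0.01 on all 12 arrays, which changes both parts of the filter, gave 2796, 1061, 1339, 273 and 14, and 1498 for T350A re-expression minus si-Control. For T350A re-expression minus si-EZH2 and T350A minus EZH2 re-expression, no filter gave 54 and 4, and 1 probe per gene 99 and 6. For all of these the cause was not tested.

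Chip section as a covariate lowered the 4-group count to 697, and gave 384 for si-EZH2 minus si-Control, 354 for EZH2 re-expression minus si-EZH2, 15 for T350A re-expression minus si-EZH2 and 282 for EZH2 re-expression minus si-Control. Only the groups compared, with fewer arrays to estimate the spread, gave 408, 405 and 3 for the same first 3 comparisons and, for T350A re-expression minus si-Control, 313. Array weights gave 14 for T350A re-expression minus si-EZH2; the cause was not tested. A fold of at least 1.5, a stricter threshold by construction, gave 303, 236, 491 and 290 for si-EZH2 minus si-Control, EZH2 re-expression minus si-EZH2, and EZH2 and T350A re-expression minus si-Control. Median scaling kept these counts within 1.5 times but moved the share of higher calls from 54.8% to 39.1%, 52.2% to 37.6%, 49.7% to 23.6% and 49.0% to 27.2% in those 4 comparisons, with a shift of the median of all probes of at most -0.0651 on the log2 scale; the cause was not tested.

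The replicate number as a block gave 12 in place of 24 for T350A re-expression minus si-EZH2. Deviations of arrays with the same number correlated between -0.0363 and 0.0709, and 6 of 12 arrays correlated best with their own number, so the numbers were not taken to pair samples.

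Between T350A and EZH2 re-expression, the raised set passed a camera p of 0.05 before adjustment with only the groups compared (median 0.0255) and with a fold of at least 1.5 (median 0.0303); the cause was not tested. With probes chosen on 2 si-EZH2 arrays and measured on the left-out one, the lowered set moved to 0.0824 with EZH2 and 0.108 with T350A.

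Leaving out each array in turn, which lowers the number of arrays, gave 870 to 1492 for the 4 groups, 396 to 644 for si-EZH2 minus si-Control, 203 to 681 and 5 to 31 for EZH2 and T350A re-expression minus si-EZH2, 1 to 3 between the re-expressions, and 823 to 1700 and 344 to 852 for EZH2 and T350A re-expression minus si-Control. The raised set gave 0.00275 to 0.0303 between the re-expressions, and -0.296 to -0.217 and -0.257 to -0.191 for EZH2 and T350A re-expression minus si-EZH2. The lowered set, not called between the re-expressions and with a median of -0.000739 there, gave 0.00109 to 0.0441, and then 0.129 to 0.223 and 0.145 to 0.247.

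Of 851 values for the 37 list calls, 791 kept their side of the threshold and 60 lost it, as did 3429 and 452 of 3881 for the 170 calls of named genes. The section covariate ended 53 gene calls and 8 list calls. With the stricter filter some named probes, 2 of them for EZH2, had no value. In simulated data 68.7% of 1.5-fold changes were recovered.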

Other observations

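The test of siRNA effects that do not pass through the EZH2 transcript level was chosen only after the result was seen, and the other tests of this part were set beforehand.

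Probes raised by the knockdown stayed above si-Control with re-expression while EZH2 probes ILMN_1652913 and ILMN_2364529 read above si-Control and ILMN_1708105 below it. Which probes read the transgene was judged after their values were seen. Noise of the shared si-Control arrays was argued against by probes chosen on 2 of those arrays and measured against the left-out one, with a mean median of 0.425 (SD 0.0388). With section as a linear covariate the median was 0.394 for EZH2 re-expression. This cannot decide on position on the chip, because that group and si-Control shared no range of sections and the probes were chosen without the covariate. T350A replicates 1 and 2 lay in sections B and D, among those of si-Control. Their means over the raised set were 0.458 and 0.466 above si-Control, which argues against position for these arrays. The siRNA effects that do not pass through the EZH2 transcript level stay open and cannot be told apart, because the median of 0.413 with EZH2 re-expression is the pattern itself and no value here separates them from other causes. Incomplete return of EZH2 protein and effects of the transgene itself were not tested.

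The same probes fell from si-EZH2 with re-expression. Noise of the shared si-EZH2 arrays as the whole cause was argued against by probes chosen on 2 of those arrays and measured against the left-out one, with a mean median of -0.203 (SD 0.0376) over both re-expression groups.

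A hypothesis was that T350A moves the same probes as EZH2 in the same direction, by over 50% of the shift. With probes chosen on 2 si-EZH2 and 2 EZH2 re-expression arrays and measured on the others, T350A gave 54.7% of the shift on average over 9 choices and both directions. In every choice the T350A median had the same direction. Both shifts were measured against the same left-out si-EZH2 array, and every choice used the same T350A arrays, so the choices are not independent. They held 14 to 123 probes that rose and 18 to 93 that fell, with equal weight, and EZH2 probes were not removed. The range was 45.8% to 56.2% for probes that rose and 52.1% to 64.3% for those that fell. The share was thus over 50% in every choice only for the probes that fell, and the test did not decide on the size. Probes were chosen by their shift with EZH2 re-expression, and no choice on T350A arrays was made. A lower shift may also follow from the lower T350A transcript level, which the design confounds with the mutation.

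For the 4-group result, 1 of 100 partitions, the real one, gave as many as 1591 probes, and the highest of the others gave 486. This argues against a chance division of these arrays, although 1 of 100 is the smallest share the test could give. Replicates are not stated to be separate cultures, so the test does not cover chance differences between cultures. For the pairwise counts 10 splits are too few for a share under 0.05. The real value and the highest other were 663 and 0 for si-EZH2 minus si-Control, 671 and 0 for EZH2 re-expression minus si-EZH2, and 24 and 0 for T350A re-expression minus si-EZH2. They were 1688 and 0 for EZH2 re-expression minus si-Control and 830 and 0 for T350A re-expression minus si-Control.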
